A study of Mus musculus with 182 samples.

How the data were processed

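RNA was measured in 182 single mouse cells, each of them 1 sample: oocytes, and blastomeres of embryos at the 2-, 4-, 8-, 16-, 32- and 64-cell stages (2C to 64C). Per the labels' protocols, embryos came from natural matings without culture. Polyadenylated RNA of each cell was reverse transcribed from the 3′ end, amplified, and sequenced as single-end reads of 50 bases. Embryos were hybrids of C57BL/6J (B6) and Cast/EiJ (Cast), written BC for a B6 mother and a Cast father and CB for a Cast mother and a B6 father. Wild-type cells came from both crosses, and cells labelled with a deletion of the paternal Xist allele (called mutant here) from CB alone.

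Genome build mm10, TopHat2 2.1.0, HTSeq 0.6.1 and SAMtools are named in the submitters' processing notes. The settings of each step, and whether counting used the strand, are not given in the sources used here. The authors deposited raw read counts for 24499 genes per cell, which are whole numbers with totals that differ between cells. The authors also deposited a second table, a signal normalized for depth and for a gene length and named RPRT, an abbreviation that its header does not spell out, for 20711 genes. Another table deposited by the authors gives an allelic fraction per gene and cell for 15253 genes, 514 of them X-linked. It was read as the share of allele-assigned reads that come from the paternal allele, because it lies near 0 for X-linked genes in males of both crosses and near 1 for Xist in wild-type females. The number of reads behind each share is unknown, so no interval can be given for a share. Wild-type and mutant cells stand in separate sheets, and no sequencing batch is named, so collection and genotype cannot be told apart.

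The labels give each cell's stage, cross, sex and genotype and name no embryo. Some titles add a letter to a number that several cells share, and the labels do not say what either marks. Cells were therefore not treated as replicates. The counts of all cells with the same 4 labels were summed into 31 groups of 1 to 25 cells, and 1 group was 1 sample. Stages, or pairs of stage and cross or of stage and sex, served as blocks, since groups of different stages come from different embryos. The p-values therefore measure the spread between groups, some of which hold 1 cell, and that spread mixes embryos with technical variation. Between stages it also mixes sex and cross, unless these were added as covariates. A cell labelled as a 2-cell female carries CB in its title and BC in its strain label. Its title was followed, and leaving it out was tried.

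Total counts ranged from 2.54M to 40.05M per cell, with a median of 8.78M. Amplified reads without molecular identifiers are not independent molecules, so floors cover counting error only. A fold against a group of samples without reads was computed against a floor of 3 counts over that group and is written as at least that size. Every cell was compared with the other cells of its group, and no pair agreed within counting noise. The closest pair, Cast oocytes 10 and 12, had a chi-square of 16.1 per degree of freedom.

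Differences in expression were tested with edgeR 4.0.16 (quasi-likelihood test, trimmed mean of M-values, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. Mutant and wild-type CB females were compared over 8C to 64C with stage as a block (14304 genes), CB males over 32C and 64C (11147 genes), and the interaction of sex and genotype over the same 2 stages (13321 genes). Wild-type females and males were compared over 11 pairs of stage and cross (16269 genes), BC and CB wild types over 11 pairs of stage and sex (16171 genes), and consecutive stages over all wild-type groups in a single fit (16622 genes). Allelic shares per gene were tested with limma 3.58.1. A cell's paternal X share was the mean over X-linked genes with at least 10 reads in that cell, and a group's share the median over its cells. X dosage was the median log2 change of X-linked genes minus that of autosomal genes, on CPM plus a pseudocount of 1, within a pair. Shares and dosage were compared by exact two-sided permutation tests of paired differences, which give no p below 0.13 with 4 pairs, and the trend over stages by permutation tests with 100000 resamples or by exact enumeration of 6 groups. The relation of share and distance from Xist was tested with 10000 resamples.

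Gene lists were written from general knowledge before the data were examined: oocyte, 2-cell activation, pluripotency, trophectoderm, primitive endoderm, cumulus and granulosa, ribosomal protein, cell cycle, DNA methylation, polycomb and chromatin, p53 and stress, FGF and ERK feedback, imprinted (paternally and maternally expressed), X-inactivation centre, X escape, X housekeeping, all X-linked and Y-linked genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Genes were named by a rule fixed at the same time: Xist and Y-linked genes; the 8 genes that rose and the 8 that fell most among those passing with the same direction in every pair (for stages, no overlap between the groups of the 2 stages); up to 4 passing members per list; for shares, members of the X and imprinted lists and the 5 highest and 5 lowest X-linked genes at 64C. Coordinates are those of the GRCm38.p6 annotation, the build of the files. Chromosomes came from the deposited tables for 20711 genes and from the annotation for 3666 more. The Y-linked and X-linked lists and the all X-linked set follow those assignments.

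The test was checked on counts simulated from the real means, with 100 genes changed 4-fold and 100 changed 16-fold. For mutant against wild-type females it recovered 20 and 46 genes of each 100, for females against males 29 and 57, for the crosses 28 and 55, for CB males 5 and 32, for the interaction 5 and 34, for 2C to 4C 2 and 23, and for 32C to 64C 3 and 28. Other genes called numbered 9, 4, 3, 0, 17, 0 and 1. The genes tested numbered 13938, 15830, 15637, 10760, 13069, 16004 and 16007. In the limma test of shares over 4881 genes, 0 of 200 genes shifted by 0.3 and 117 of 200 shifted by 0.6 were recovered, with 3 other genes called at the larger shift.

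Alternatives were size factors of the DESeq2 kind (RLE), DESeq2 1.42.0 itself, no filter on low counts, limma on means over cells of log2(CPM + 1), each stage or group left out in turn, other read minimums, and the authors' normalized signal in place of counts. Other settings were added after the data had been seen: leaving out 2 mutant 8C cells with Xist reads, the trend over 4C to 64C alone, and X dosage in males. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. Reads and sequence variants were not used here.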

Results

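The 182 cells comprised 7 oocytes (4 of B6 and 3 of Cast), 106 wild-type blastomeres and 69 blastomeres of embryos labelled with a deletion of the Xist allele inherited from the father. Wild-type females numbered 3 cells at 2C, 8 at 4C, 23 at 8C, 11 at 16C, 14 at 32C and 12 at 64C, and wild-type males 3, 2, 6, 4, 12 and 8. Females labelled mutant numbered 7 at 8C, 12 at 16C, 16 at 32C and 25 at 64C, and males labelled mutant 4 at 32C and 5 at 64C. The total count per cell ranged from 2.54M to 40.05M (M for mega), with a median of 8.78M. Within groups, the correlation of log2 expression between cells ranged from 0.649 to 0.981.

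The targeted gene came first, because it checks the labels. Xist (X chromosome, 103460373 to 103483233) is the long noncoding RNA that coats and silences an X chromosome, and before implantation in the mouse it comes from the paternal X. Wild-type females had 2.16 (BC) and 1.59 (CB) CPM at 2C, then 103 and 56.7 at 4C, 188 and 35.5 at 8C, 63.7 and 88.9 at 16C, 262 and 125 at 32C, and 795 and 115 at 64C. Its paternal share in wild-type females was 0.994 at 4C and 0.985 at 64C. Females labelled mutant had 0.170 CPM at 16C (highest cell 1.40), 0.167 at 32C (highest cell 0.584) and 0.920 at 64C (highest cell 8.51). At 8C, 5 of their 7 cells had at most 2.17 CPM, but cell 7 had 162 counts (21.2 CPM) and cell 9 had 428 counts (80.6 CPM), with paternal shares of 1.0 and 0.858. These 2 cells go against their label, so the groups are called labelled mutant, and results were also computed without them. Xist was lower in females labelled mutant in 4 of 4 stages (log2 change -7.41, SE 1.53; edgeR p = 0.000706, adjusted p = 1). Male groups had at most 3.26 CPM of Xist. Every male cell had at least 13 Y-linked counts, and female cells had 65 at most. These ranges overlap, so the count alone does not separate the sexes in every cell.

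**Figure D1:**
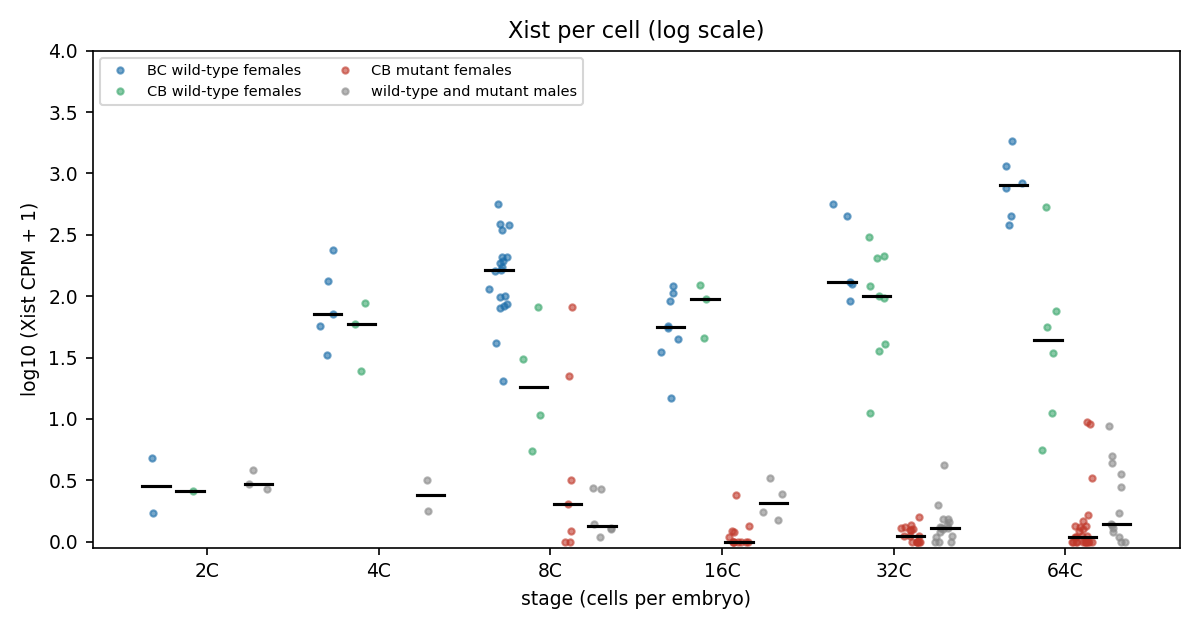
Xist per cell as log10 (CPM + 1) by stage, with 1 point per cell and a bar at the median of each group of cells. Wild-type females of BC reach a median of 803 CPM at 64C, while females labelled mutant have a median of 0.098 CPM there, and cells 7 and 9 at 8C stand at 21.2 and 80.6 CPM.

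Paternal expression of X-linked genes in wild-type females, the measure of imprinted X inactivation, fell with stage. The median paternal share of X-linked reads in BC and CB females was 0.387 and 0.466 at 2C, 0.403 and 0.509 at 4C, 0.413 and 0.457 at 8C, 0.303 and 0.338 at 16C, 0.270 and 0.350 at 32C, and 0.183 and 0.162 at 64C. Wild-type males, which carry no paternal X, had 0.0165 ± 0.0178 (SD, n = 11 groups), the background of the measure. Over the 12 female groups the share fell with the log2 cell number (Pearson's r = -0.853, permutation p = 0.00049; Spearman's rho = -0.834, permutation p = 0.00146). Both p-values are two-sided. The groups of 2C and 64C lie equally far from the middle of the stages: r was -0.915 without 2C and -0.726 (permutation p = 0.0205) without 64C. In BC alone r was -0.899 (exact p = 0.025, n = 6; -0.919 without 2 groups) and rho -0.771 (exact p = 0.103, n = 6). In CB alone r was -0.893 (exact p = 0.0167, n = 6; -0.924 without 2 groups) and rho -0.886 (exact p = 0.0333, n = 6). The 3 relations form a single family, and the rank correlation within BC did not pass 0.05.

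In females labelled mutant the paternal share of X-linked reads stayed near equal expression of both alleles: 0.503 at 8C, 0.504 at 16C, 0.505 at 32C and 0.495 at 64C (0.502 ± 0.0047, SD, n = 4 groups). CB wild-type females had 0.327 ± 0.122 (SD, n = 4 groups). The difference, 0.175 ± 0.118 (SD, n = 4), was 0.046 at 8C, 0.167 at 16C, 0.154 at 32C and 0.333 at 64C. It lay above 0 in 4 of 4 stages, and the exact two-sided p of 0.13 is the smallest that 4 pairs allow. Males labelled mutant stayed at 0.0105 ± 0.0006 (SD, n = 2 groups). The paternal share of autosomal reads in females labelled mutant was 0.50 ± 0.0145 (SD, n = 4 groups).

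**Figure D2:**
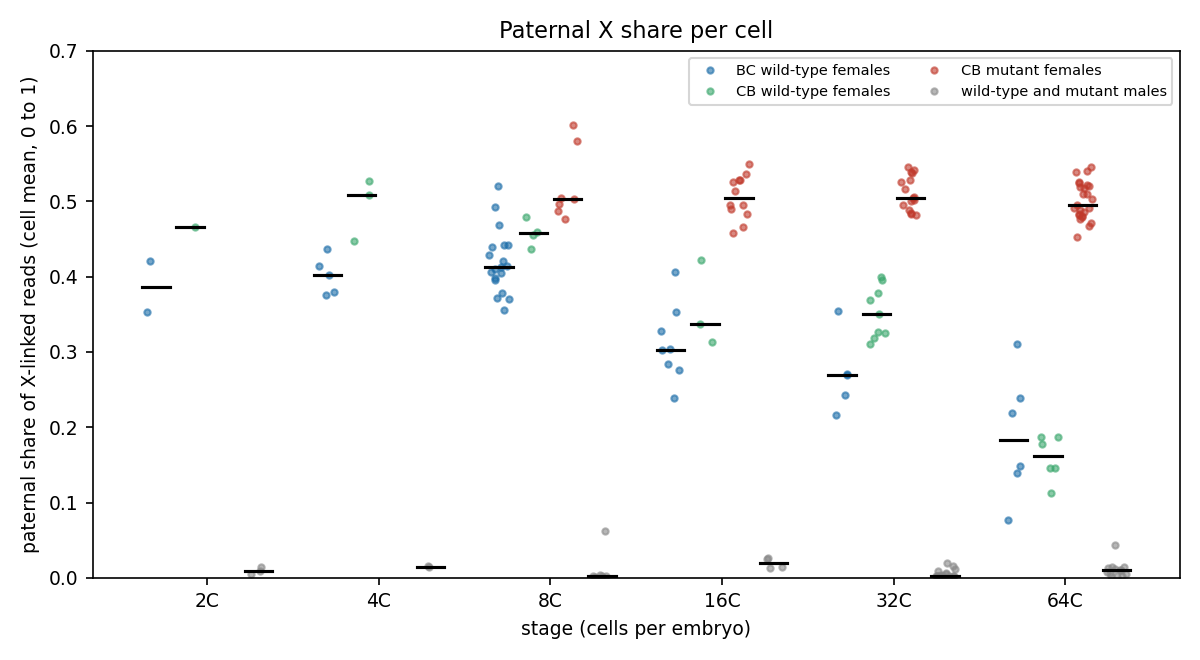
Paternal share of X-linked reads (0 to 1) per cell by stage, with 1 point per cell and a bar at the median. Wild-type females go from 0.413 (BC) and 0.457 (CB) at 8C to 0.183 and 0.162 at 64C, females labelled mutant stay between 0.495 and 0.505, and males lie near 0.

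Genes with a paternal share of at most 0.15 became more frequent on the X of wild-type females. Of 109 X-linked genes measured in every wild-type female group from 8C on, 5 in BC and 11 in CB lay at or below 0.15 at 8C, 16 and 26 at 16C, 32 and 13 at 32C, and 50 and 56 at 64C. Of 4766 autosomal genes, 352 (BC) and 257 (CB) did so at 64C, and 189 and 452 at 8C. The 11 X-linked genes of CB at 8C (10.1%) were thus near the autosomal rate (9.48%). In the 125 X-linked genes measured in both genotypes, 70 wild-type CB genes lay at or below 0.15 at 64C against 2 in females labelled mutant. Of 4756 autosomal genes 310 and 61 did so, in groups of 6 and 25 cells, so part of that gap may follow from the number of cells. The number of reads behind each share is unknown.

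Gene by gene, 47 of 125 X-linked genes (37.6%) had a higher paternal share in females labelled mutant in each of 4 stages, against 268 of 4756 autosomal genes (5.64%). Chance gives 6.25% for 4 signs. The median difference was 0.167 over X-linked genes and -0.0067 over autosomal genes. The largest evidence was at Pdzd11 (difference 0.374, SE 0.0534; 0.168 in wild type, 0.542 in mutant) and Rlim (0.367, SE 0.0525; 0.0908 in wild type, 0.458 in mutant), which encodes a ubiquitin ligase that activates Xist. Acsl4 (0.432, SE 0.0712), an acyl-CoA synthetase, Magt1 (0.39, SE 0.065), a magnesium transporter, Kif4 (0.363, SE 0.0702), a chromosome-associated kinesin, and Zfx (0.443, SE 0.0859), a zinc-finger factor with a Y homologue, also differed in 4 of 4 stages. With limma, 0 of the 125 X-linked and 0 of the 4756 autosomal genes passed over all genes, 240 had an unadjusted p under 0.05, and 39 of those were X-linked and higher in mutants. Adjusted over the list alone, 13 X-linked genes passed: Pdzd11, Rlim, Acsl4, Igbp1, Magt1, Pim2, Hcfc1, Taz, Kif4, Wdr13, Zfx, Cited1 and Rab9, a naming chosen after their values were seen. Their adjusted p over the X alone ranged from 0.0316 to 0.0347.

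At 64C, the lowest paternal shares of wild-type females among 91 X-linked genes measured in at least 3 cells of each cross were 0 at Apex2, Timp1 and Tmem185a, 0.001 at Pgk1 and 0.0015 at Pnma5. In females labelled mutant the same genes had 0.625, 0.686, 0.425, 0.572 and 0.501. Pgk1, the glycolytic phosphoglycerate kinase (X chromosome, 106187100 to 106203699), stood at 0.462 in BC females at 8C, and Apex2, a DNA repair nuclease, at 0.523, while Pnma5 had 0.261, Timp1 0.0809 and Tmem185a 0 at that stage. In CB females at 8C Apex2 had 0.5 and Timp1 0. The highest shares were 0.985 at Xist, 0.571 at Yipf6, 0.57 at 1810030O07Rik, 0.457 at Ogt, the O-GlcNAc transferase, and 0.455 at Kdm5c, a histone demethylase known to escape inactivation. Behind these means, Ogt, Yipf6, 1810030O07Rik and Kdm5c had 0.727, 0.957, 0.241 and 0.577 in BC and 0.187, 0.185, 0.9 and 0.333 in CB. Each of these values comes from 3 to 6 cells per cross without a test.

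Genes known to escape inactivation in somatic cells had mean paternal shares at 64C of 0.466 (Kdm6a), 0.396 (Eif2s3x), 0.347 (Pbdc1) and 0.306 (Ddx3x), as means of BC and CB wild-type females. Kdm6a was measured in 1 BC and 3 CB cells and Ddx3x in 2 and 4, so both miss the minimum of 3 cells in BC. The corresponding shares in females labelled mutant were 0.369, 0.639, 0.426 and 0.449. The crosses lay apart: Kdm6a was at 0.712 in BC and 0.219 in CB, and Ddx3x, an RNA helicase, at 0.594 in BC and 0.018 in CB. Ddx3x thus had few paternal reads in CB. Around Xist, Rlim went from 0.495 at 2C to 0.224 at 4C, 0.102 at 8C, 0.0728 at 16C, 0.041 at 32C and 0.0498 at 64C, and stood between 0.442 and 0.477 in females labelled mutant. Atp7a, a copper transporter, was at 0.309 at 8C and at 0 from 16C on. Among other housekeeping genes, Magt1 went from 0.381 at 8C to 0.0411 at 64C, Nono, a paraspeckle protein, from 0.466 to 0.0592, Hprt, a purine salvage enzyme, from 0.482 to 0.151, and Huwe1, a ubiquitin ligase, from 0.499 to 0.194. Pdha1 (0.438 and 0.333) and Lamp2 (0.472 and 0.28) had values closer together, and at 64C stood near those of Pbdc1 and Ddx3x. These shares are single group means, and their order over stages was not tested per gene.

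**Figure D3:**
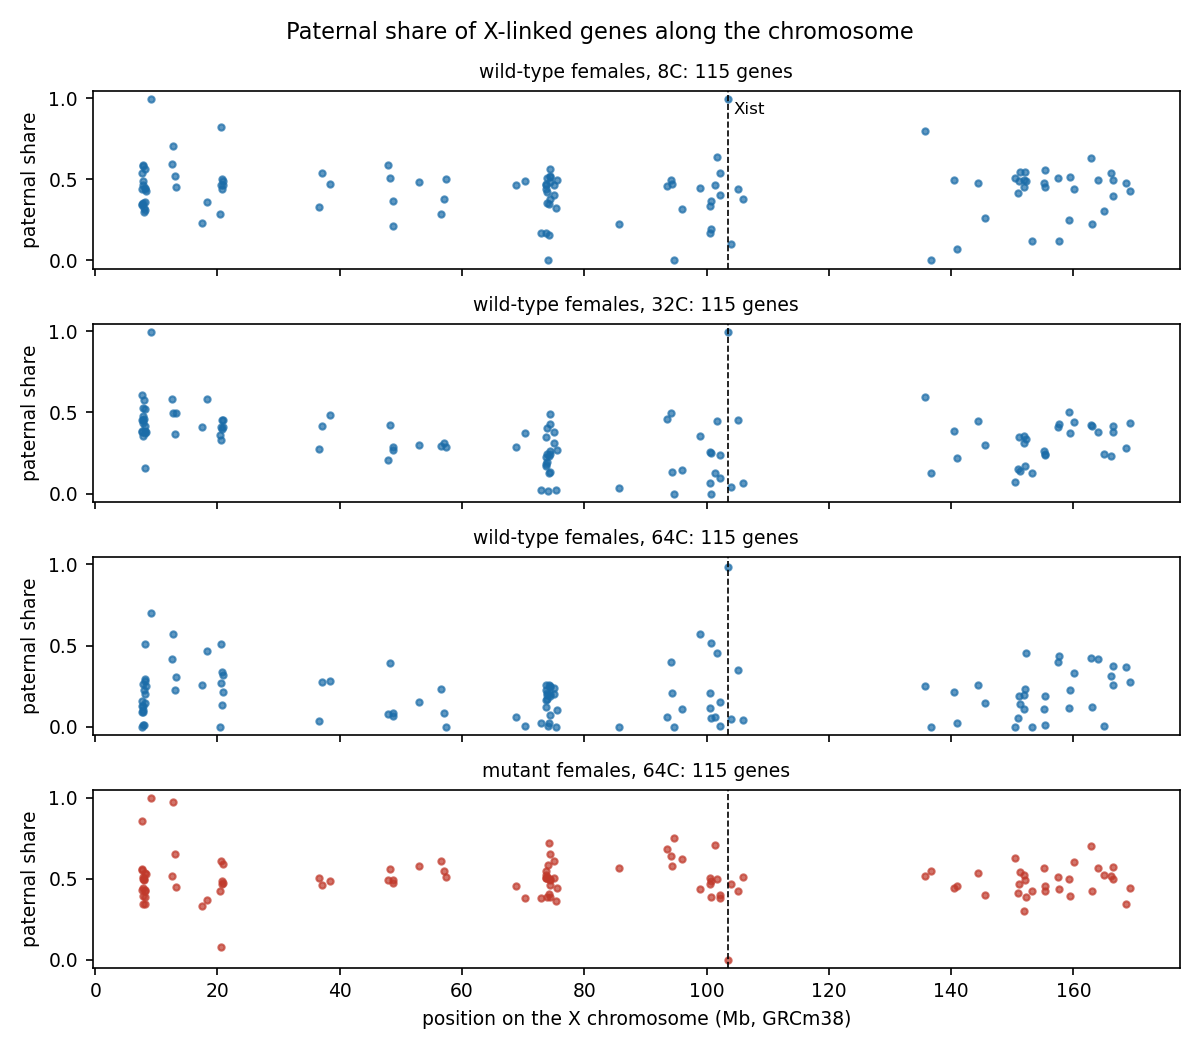
Paternal share (0 to 1) of X-linked genes against their position on the X chromosome in Mb, with 1 point per gene and the position of Xist as a dashed line, for wild-type females (mean of BC and CB) at 8C, 32C and 64C and females labelled mutant at 64C. The mean X share of the 2 wild-type groups is 0.435 at 8C, 0.310 at 32C and 0.173 at 64C, and that of females labelled mutant 0.495 at 64C.

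Imprinted autosomal genes provided an allelic reference from 8C to 64C. Slc38a4, an amino acid transporter, had a paternal share of 0.996 ± 0.0075 in BC (SD, n = 8 groups), 0.995 ± 0.0053 in CB (n = 6) and 0.998 ± 0.0015 in groups labelled mutant (n = 6). Sfmbt2 (0.999, 0.997 and 0.999), Mcts2 (0.994, 0.999 and 0.993), Jade1 (0.991, 0.988 and 0.902), Gab1 (0.975, 0.932 and 0.994), Smoc1 (0.944, 0.998 and 0.993), Zrsr1 (0.971, 1.0 and 1.0) and Impact (0.932, 0.867 and 0.966) likewise came from the paternal allele in BC, CB and mutant groups in turn. Meg3, a maternally expressed long noncoding RNA, had 0.0357, 0 and 0.0002. Other listed genes had reads of both alleles: H13 (0.425, 0.388 and 0.369), Blcap (0.529, 0.381 and 0.601), Inpp5f (0.731, 0.548 and 0.466), Igf2r (0.484, 0.401 and 0.289), Ube3a (0.273, 0.597 and 0.431), Gnas (0.299, 0.435 and 0.538), Mest (0.667, 0.901 and 0.892) and Grb10 (0.631, 0.0167 and 0.541). In CB, Grb10 reads were nearly all maternal. The SDs of Mest and Grb10 between groups reached 0.471 and 0.413, over 2 to 5 groups each. Values of the crosses also lay apart, as at Grb10, at Usp29 (0.833 in BC, 0.149 in CB), Trappc9 (0.206 in BC, 0.832 in CB) and Kcnq1ot1 (0.425 in BC, 0.822 in CB). Groups labelled mutant, all of CB, had 0.254, 0.794 and 0.703 at the last 3 genes. The father is Cast in BC and B6 in CB. Mean Usp29 reads thus came mostly from the Cast allele in both crosses, and Trappc9 reads mostly from the B6 allele. Over 2C and 4C the means were 0.437 at Mest, 0.122 at Blcap and 0.0791 at Ube3a (3, 6 and 6 groups). No test was run on these shares.

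Autosomal reads of wild types reached equal shares by 16C. Their paternal share was 0.0122 ± 0.0083 in oocytes (SD, n = 2 groups), 0.364 ± 0.0592 at 2C (n = 4), 0.439 ± 0.0171 at 4C (n = 3), 0.468 ± 0.0374 at 8C (n = 4), 0.497 ± 0.0197 at 16C (n = 4), 0.502 ± 0.0174 at 32C (n = 4) and 0.511 ± 0.0086 at 64C (n = 4). From 16C to 64C it was 0.491 ± 0.013 in BC and 0.516 ± 0.0043 in CB (SD, n = 6 groups each). Maternal RNA carried over from the oocyte counts as maternal reads at the first stages, so the X shares of 2C and 4C include it.

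X-linked genes stood higher in females labelled mutant than in wild-type females. The median log2 change of X-linked genes exceeded that of autosomal genes by 0.42 at 8C, 0.36 at 16C, 0.23 at 32C and 0.50 at 64C (mean 0.38 ± 0.11, SD, n = 4 stages), with 530 X-linked and 13765 autosomal genes. It was above 0 in 4 of 4 stages, and the exact p of 0.13 is the smallest possible with 4 pairs. Among genes with a mean of at least 100 CPM, 76 of them X-linked, the excess was 0.48 ± 0.18 (SD, n = 4). In males the same measure was 0.04 ± 0.06 (SD, n = 2 stages), and -0.06 ± 0.21 for genes of at least 100 CPM. This male comparison was added after the data had been seen. The excess did not follow the difference in paternal share by stage: 0.42 at 8C stood beside 0.046, and 0.23 at 32C beside 0.154. X escape genes had a median log2 change of 0.573 (7 tested), near the 0.593 of X housekeeping genes (39 tested). At 8C the sum labelled mutant also had a 2-cell activation level of 2.22, against at most 1.84 in wild-type groups. Whether a difference in developmental timing contributed was not tested.

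Wild-type females exceeded males in X-linked expression. The order of the stages was not tested. Among genes with a mean of at least 100 CPM (65 X-linked, 2014 autosomal), the excess was 0.81 (BC) and 0.87 (CB) at 2C, 0.85 at 4C (BC), 0.86 and 0.27 at 8C, 0.51 and 0.33 at 16C, 0.40 and 0.56 at 32C, and 0.20 and 0.32 at 64C. It lay above 0 in 11 of 11 pairs (mean 0.54 ± 0.26, SD, n = 11; permutation p = 0.000977, the smallest possible). Over all 603 X-linked genes passing the filter the mean was 0.11 ± 0.17 (SD, n = 11; permutation p = 0.0391), above 0 in 7 pairs, while 3 pairs had a median of 0 in both sets. With the authors' normalized signal it was 0.14 (permutation p = 0.0781), so this call over all genes was not kept. That signal also differs in its scaling for gene length and covers 595 of the X-linked genes. On the fitted scale of edgeR, the median log2 change was 0.775 over the 603 X-linked genes and 0.173 over autosomal genes. Of these, 81.26% and 61.57% lay above 0, so the size of the excess depends on the measure.

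**Figure D4:**
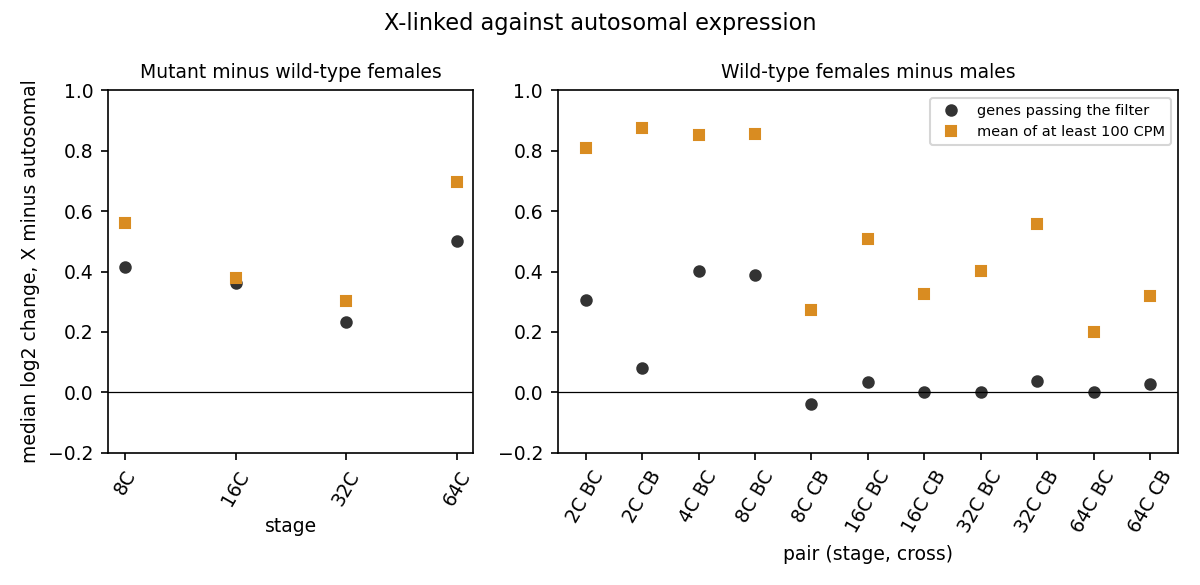
Median log2 change of X-linked minus that of autosomal genes, per stage for females labelled mutant against wild type and per pair of stage and cross for wild-type females against males. Squares (mean of at least 100 CPM) go from 0.87 at 2C in CB to 0.20 at 64C in BC for females against males, and all circles of the mutant comparison lie between 0.23 and 0.50.

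Gene expression of females labelled mutant was compared with that of wild-type CB females over 8C to 64C. X-linked genes lay higher: 443 of 530 (83.6%) had a log2 change above 0, against 7574 of 13765 autosomal genes (55.02%). Camera called all X-linked genes (adjusted p = 1.33e-12) and the X housekeeping list (adjusted p = 4.76e-06) higher, with adjusted p = 0.529 and adjusted p = 0.545 with an estimated correlation. In the X-inactivation centre list, 4 genes rose and 1 fell of 9 tested, adjusted over the list alone. They are Xist on the falling side and Rlim (1.41, SE 0.374), Chic1 (3.27, SE 1.054), Tsix (6.52, SE 2.09) and Ftx (5.18, SE 1.81) on the other, and camera gave an adjusted p of 0.0154 (adjusted p = 0.529 with an estimated correlation). Tsix is transcribed antisense through Xist, and the strand of the counts is not known. Xist reads counted as Tsix would not give this rise, since Xist fell (-7.41, SE 1.53).

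Oocyte genes (camera adjusted p = 0.000713; 20 tested) and 2-cell activation genes (camera adjusted p = 0.0154; 12 tested) stood higher in females labelled mutant, and ribosomal protein genes lower (camera adjusted p = 0.022; 20 tested). With an estimated correlation these became adjusted p = 0.545, adjusted p = 0.681 and adjusted p = 0.681, and no member passed, also adjusted over the list alone. The remaining lists, pluripotency, trophectoderm and primitive endoderm among them, did not pass. With edgeR 0 of 14304 genes passed, Xist included, while 532 had an unadjusted p under 0.05. DESeq2 called 176 genes higher, 29 of them X-linked, and 26 lower, and limma on cell means called 0. The test recovered 46 of 100 genes changed 16-fold in simulated counts of this size. Without the 2 mutant cells with Xist reads, Xist had a log2 change of -7.94 (SE 0.881, edgeR adjusted p = 0.145).

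Males carry no paternal X and served as the background for differences between the collections. Camera called trophectoderm genes (18 tested, adjusted p = 0.000135) and ribosomal protein genes (20 tested, adjusted p = 0.0138) higher and primitive endoderm genes (17 tested, adjusted p = 0.0138) lower in males labelled mutant, each with adjusted p = 0.998 with an estimated correlation. Krt18 (log2 change 3.31, SE 0.608), Krt8 (2.69, SE 0.646), both keratins of the trophectoderm, and the tetraspanin gene Tspan8 (3.72, SE 0.939) were higher in 2 of 2 stages, and 3 trophectoderm genes rose adjusted over the list alone (edgeR adjusted p = 1 over all genes). The wild-type CB males at 64C, 2 cells, had a mean trophectoderm level of 3.50 on the log2 scale, against 6.11 to 6.90 in the other wild-type groups of that stage and 5.10 in males labelled mutant. No X list passed, and 1 gene of the FGF and ERK feedback list was higher adjusted over the list alone. EdgeR called 0 of 11147 genes (348 at an unadjusted p under 0.05), DESeq2 183 higher and 126 lower, and limma on cell means 4.

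The interaction of sex and genotype at 32C and 64C asks whether the difference between groups labelled mutant and wild type was unlike in females and males. Males carry no paternal X, so their difference is not an effect of the deletion. Xist had the lower change in females (-6.50, SE 1.89, edgeR adjusted p = 0.926). Trophectoderm genes (camera adjusted p = 1.33e-05) and ribosomal protein genes (0.00152) had a lower difference by label in females than in males. Primitive endoderm (0.0113) and pluripotency genes (0.0243) had a higher one. All 4 had adjusted p = 0.848 with an estimated correlation, and the wild-type males of 64C in this test are the 2 cells described above. Adjusted over the list alone, 2 trophectoderm genes and 1 gene of the FGF and ERK feedback list passed. All X-linked genes did not pass (camera adjusted p = 0.266). EdgeR called 0 of 13321 genes, 616 at an unadjusted p under 0.05, and DESeq2 125 higher and 122 lower.

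Wild-type females and males differed at Xist and at Y-linked genes first. Xist rose in females by 6.23 on the log2 scale (SE 1.029, edgeR adjusted p = 0.0413), in 10 of 11 pairs. Eif2s3y, a translation initiation factor gene of the Y, fell by 9.35 (SE 0.65, edgeR adjusted p = 3.02e-08) in 11 of 11 pairs, and Ddx3y, an RNA helicase gene, by 7.79 (SE 1.34, edgeR adjusted p = 0.0342). The other 2 genes called were X-linked ferritin-like genes, named after their values were seen: Fthl17-ps1 (6.06, SE 1.01, edgeR adjusted p = 0.0342) and Fthl17d (5.65, SE 0.965, edgeR adjusted p = 0.0342). They belong to a family of near-identical copies, so the division of reads among the copies is uncertain. In all, 3 genes rose and 2 fell with edgeR of 16269 tested, 850 had an unadjusted p under 0.05, and DESeq2 called 61 higher and 13 lower. RLE factors moved the median of all genes by -0.102 and called the same 5 genes. With a stage left out, the count fell to 1 without 8C, 16C or 32C and to 2 without 4C.

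X-linked lists rose in wild-type females with both correlations. All X-linked genes passed with camera (adjusted p = 4.04e-10; adjusted p = 0.0248 with an estimated correlation), and 36 of 603 rose adjusted over the list alone. The X housekeeping list passed (adjusted p = 3.62e-08; adjusted p = 0.013 with an estimated correlation; 8 of 39 rose adjusted over the list alone). So did genes known to escape inactivation (adjusted p = 5.2e-05; adjusted p = 0.0111 with an estimated correlation; 4 of 7 rose adjusted over the list alone), such as Kdm6a (log2 change 1.76, SE 0.572) and Kdm5c (0.97, SE 0.373), which did not pass over all genes. Y-linked genes fell (adjusted p = 2.77e-23; adjusted p = 0.000282 with an estimated correlation; 7 of 8 adjusted over the list alone). Oocyte genes were lower with camera (adjusted p = 0.0212; adjusted p = 0.501 with an estimated correlation) and no other list passed.

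The reciprocal crosses share their autosomal genotype and differ in parent of origin and in the mother's strain. BC exceeded CB in Omt2b (log2 change 2.61, SE 0.371, edgeR adjusted p = 0.00666) and in Khdc1b (2.03, SE 0.339, edgeR adjusted p = 0.0419), a gene of an oocyte KH-domain family, each in 11 of 11 pairs. Lncenc1, a long noncoding RNA of pluripotent cells, named after its value was seen, was lower in BC (-9.42, SE 1.04, edgeR adjusted p = 0.000551) in 9 of 11 pairs. Cell cycle genes (camera adjusted p = 0.00101) and X housekeeping genes (0.0261) were lower in BC, with adjusted p = 0.383 and adjusted p = 0.695 with an estimated correlation, and no member of either passed adjusted over the list alone. With fry, genes of 2-cell activation, maternally expressed imprinted genes and p53 and stress genes were higher in BC (adjusted p = 0.0423 each). In lists that did not pass with camera, 2 maternally expressed imprinted genes, 1 primitive endoderm gene, 1 X escape gene and 2 of all X-linked genes were higher in BC, and 1 of all X-linked genes lower, adjusted over the list alone. Xist did not pass (0.67, SE 0.464, edgeR adjusted p = 0.588). EdgeR called 3 of 16171 genes and 1865 had an unadjusted p under 0.05. DESeq2 called 610 higher and 176 lower, and limma on cell means 0.

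From the oocyte to 2C the transcriptome changed the most: 2285 genes rose and 2191 fell (edgeR, 2 oocyte and 4 2C groups, 16622 genes). Of 20 oocyte genes 11 fell, among them H1foo, the oocyte linker histone (log2 change -8.59, SE 1.76), Mos, the kinase of meiotic arrest (-8.26, SE 1.94), Zar1 (-7.44, SE 2.07) and the growth factor gene Gdf9 (-6.39, SE 1.25). Of 19 genes of 2-cell activation 11 rose. Gm8300 went from 0.0475 CPM (1 count) to 271 ± 61.2 CPM (SD, n = 4), Zfp352 from 0.0475 CPM (1 count) to 86.6 ± 23.8, Zscan4f from 0.0853 CPM (2 counts) to 121 ± 111, and Tdpoz2 from 0 to 8.11 ± 6.37, at least 62.7-fold higher. Of 20 ribosomal protein genes 16 rose, with changes of 4.82 for Rpl13 (SE 1.49) and 4.24 for Rps20 (SE 0.972). Camera passed the 3 lists with adjusted p = 0.00181, 7.29e-07 and 1.26e-09, which became adjusted p = 0.247, 0.155 and 0.233 with an estimated correlation. Adjusted over the list alone, 12, 13 and 18 members passed.

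In the same step, 4 of 11 genes of DNA methylation fell and 1 rose (camera adjusted p = 0.044; adjusted p = 0.155 with an estimated correlation), with the demethylation enzyme Tet3 at -7.22 (SE 1.53), Uhrf1 at -5.36 (SE 0.845) and Dnmt1 at -3.43 (SE 0.733). Primitive endoderm genes fell in 7 and rose in 1 of 20 (camera adjusted p = 0.044; adjusted p = 0.513 with an estimated correlation), Lamb1 by 7.94 (SE 1.12). In lists that did not pass as a whole, Dppa4 (6.60, SE 0.752) and Zfp42 (5.66, SE 1.08) of the pluripotency list and Tead4 (5.09, SE 0.871), a trophectoderm factor, rose, while Sall4 (-4.70, SE 0.511) fell. Cdk1 (5.03, SE 0.752) and Top2a (4.94, SE 0.973) rose and Ccnb2 (-3.48, SE 0.477) fell. Trp53 fell by 5.17 (SE 1.26) and Cdkn1a, its target, rose by 4.77 (SE 1.60). The paternally expressed Jade1 rose by 7.34 (SE 1.40). Polycomb and chromatin genes rose in 3 and fell in 7 of 17, with Yy1 at 5.51 (SE 0.934), X housekeeping genes rose in 15 and fell in 4 of 39, with Prps1 at 6.00 (SE 0.852), and X escape genes fell in 3 and rose in 1 of 7, with Ddx3x at -2.98 (SE 0.565). Of cumulus and granulosa markers 2 of 11 rose and 2 fell, Serpine2 (-6.43, SE 0.969) among the latter. Rfpl4b, Gm2016, Tef, Cxcl16, Plekho2, Trib3, Ier5 and Kifc2 had no reads in oocytes and rose at least 455-fold to 1000-fold. Cd1d1, Chac2, Frmd5, Snx25, Pparg, Postn, Kdelc1 and Suox had none at 2C and fell at least 261-fold to 657-fold. RLE factors moved the median of all genes by -0.474 in this step and the split of calls to 1923 higher and 2838 lower.

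**Figure D5:**
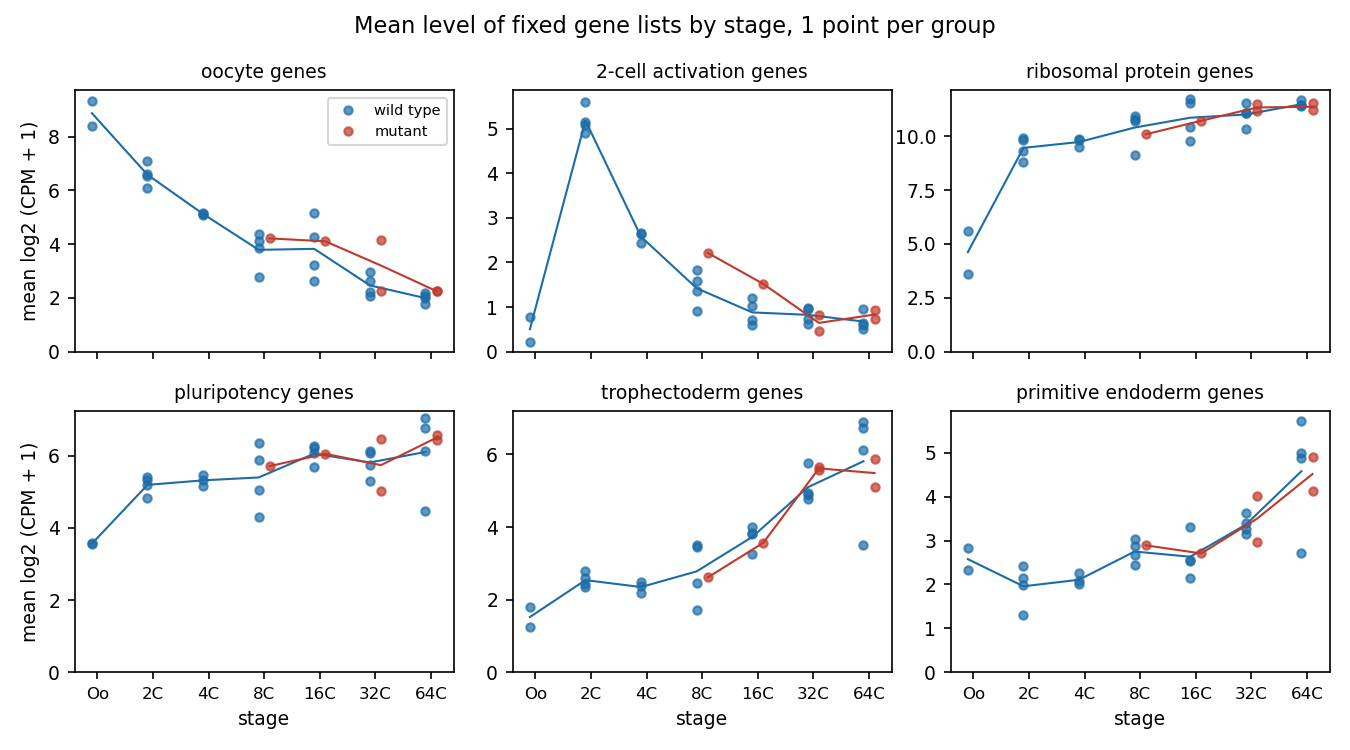
Mean log2 (CPM + 1) of 6 fixed gene lists by stage, with 1 point per group and a line through the stage means, for wild type and groups labelled mutant. Oocyte genes go from 8.88 in oocytes to 1.99 at 64C in wild types, genes of 2-cell activation peak at 5.19 at 2C, and trophectoderm genes reach 5.81 at 64C.

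From 2C to 4C, 1114 genes rose and 488 fell (edgeR, 4 and 3 groups). Of the 2-cell activation genes 6 fell and 1 rose of 19 (camera adjusted p = 0.000489; adjusted p = 0.296 with an estimated correlation; 12 fell and 1 rose adjusted over the list alone), with Usp17la (-5.199, SE 1.55), Zscan4c (-5.09, SE 1.51), Zfp352 (-5.06, SE 1.48) and Zscan4f (-4.76, SE 1.47). Tdgf1, a Nodal co-receptor, rose by 7.62 (SE 1.46), Gata6, an endoderm factor, by 4.91 (SE 0.757), Tet1 by 4.35 (SE 0.723), and Trp53 by 5.73 (SE 1.24). Sall4 rose by 2.11 (SE 0.448), Myc by 4.15 (SE 1.33) and Fgfr2, the FGF receptor of the trophectoderm, by 3.63 (SE 0.82). Krt8 fell by 5.47 (SE 1.41). Ribosomal protein (5 rose of 20, camera adjusted p = 0.0393), cell cycle (4 of 20, 0.0343), X escape (3 of 7, 0.0126) and polycomb and chromatin genes (3 rose and 1 fell of 17, 0.0393) passed, with Rpl3 at 3.99 (SE 0.593), Aurka at 2.16 (SE 0.568), Kdm6a at 4.34 (SE 1.105) and Jarid2 at 2.65 (SE 0.485). With an estimated correlation these 4 lists had adjusted p = 0.75, 0.35, 0.296 and 0.426. Nxf2, Nipsnap3b, Atp10d, Mboat1, Lbhd1, the trophoblast factor Gcm1, Itm2a and Abcb11 had no reads at 2C and rose at least 148-fold to 405-fold. Chst7, Sva, Gm4532, Usp27x, Ctf2, Gm16701 and Arhgef28 fell to 0 reads, at least 300-fold to 588-fold, and Perm1 to 1 count. The count of 1602 moved to between 849 (without the BC females of 4C) and 1987 (without the CB males of 16C) with a group left out. RLE factors moved the median by -0.219 and the split to 846 higher and 597 lower.

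From 4C to 8C, 65 genes rose and 16 fell (edgeR, 3 and 4 groups). Krt8, a keratin, rose from 0.146 ± 0.126 (SD, n = 3) to 14.5 ± 17.1 CPM (SD, n = 4; log2 change 6.62, SE 1.48), and the ribosomal protein genes Rplp0 (3.02, SE 0.696) and Rpl8 (2.65, SE 0.499) rose. Exosc5, an exosome subunit (6.36, SE 1.21), Slc4a2 (7.41, SE 1.62), the catalase gene Cat (7.202, SE 1.65) and Gsn, an actin-severing protein (no reads at 4C, at least 517-fold), also rose, as did Cdkn2c, Anxa3 and Foxc1 from 1 count each. Nlrp2 fell from 11.3 ± 4.86 CPM and Lhx8, an oocyte transcription factor, from 6.72 ± 5.20 CPM to 1 count each. Gpm6a, Myt1, Hnmt, Fa2h, C2cd5 (-3.58, SE 0.761) and Psg16 (-3.00, SE 0.571) fell as well. Ribosomal protein (adjusted p = 0.00138), primitive endoderm (0.0114), 2-cell activation (4.68e-06) and oocyte genes (0.0167) passed with camera, the last pair lower, and had adjusted p = 0.587, 0.469, 0.214 and 0.515 with an estimated correlation. Adjusted over the list alone, 3 and 6 rose in the first pair, and 2 and 0 fell in the last. The count of 81 rests on the 4C groups: without the BC males of 4C it was 0, without the BC females 1, and without the CB females 15.

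From 8C to 16C, 22 genes rose and 113 fell (edgeR, 4 groups each). Elf3, an epithelial transcription factor of the trophectoderm list, rose from 21.8 ± 21.03 to 331 ± 268 CPM (log2 change 4.05, SE 0.988), with Dlc1 (5.41, SE 1.09), Dok2 (5.30, SE 1.23), Tinagl1 (5.08, SE 1.099), Akr1b8 (4.91, SE 1.048), Adgre5 (4.80, SE 1.11), Hhex (4.29, SE 1.04) and the adhesion gene Nectin2 (3.56, SE 0.822). Pcgf6, a polycomb subunit, fell by 2.24 (SE 0.552). Col1a1, a collagen, and Vim, the intermediate filament vimentin, had 26.4 ± 29.03 and 18.2 ± 20.9 CPM at 8C and no reads at 16C, at least 547-fold and 782-fold lower. The source of these reads at 8C was not tested. Of 11 cumulus and granulosa genes, 2 fell adjusted over the list alone, while that list did not pass with camera (adjusted p = 0.505). Tex15, a germ-cell gene, fell by 9.33 (SE 1.34), as did Fam49a, Meis2, Phyhipl, Tomm40l and Slc19a3. Pluripotency (camera adjusted p = 0.0121; 5 rose adjusted over the list alone), trophectoderm (0.0188; 3 rose and 1 fell) and ribosomal protein genes (0.00735; 0) were higher, and 2-cell activation (0.0188; 0) and polycomb and chromatin genes (0.0386; 5 fell) lower. With an estimated correlation these 5 lists had adjusted p = 0.646, 0.646, 0.711, 0.646 and 0.646. The count of 135 moved to between 6 (without the BC or CB females of 16C) and 402 (without the BC males of 8C) with a group left out, and another split of the same 8 groups gave 148.

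From 16C to 32C, 34 genes rose and 71 fell (edgeR, 4 groups each). Atp12a, a proton pump of the trophectoderm list, went from 0 to 8.52 ± 6.61 CPM (at least 405-fold) and Dppa1 from 1 count to 17.8 ± 14.6 CPM. Apela, a peptide ligand of the apelin receptor, Tmprss2, a serine protease, and Rin3 went from 0 reads to 10.8 ± 8.73, 9.45 ± 13.6 and 5.82 ± 1.01 CPM, and Slc37a2 (9.77, SE 1.86), AI662270 (10.27, SE 2.11) and Tomm40l rose. Obox5, an oocyte homeobox gene, fell from 10.5 ± 18.4 CPM to 1 count, and Nr5a2, an orphan nuclear receptor, by 2.25 (SE 0.463). Gdap1, Ifi27, Rhobtb1, Fbxw16, Gng3, Fbxo47 and Tcl1b4 fell to 0 reads, at least 30.4-fold to 252-fold, and Plekhg6 to 5 counts. Oocyte genes were lower (camera adjusted p = 2.98e-07; 5 of 20 fell adjusted over the list alone), and trophectoderm (0.00426; 3 rose) and DNA methylation genes (0.0472; 1 rose) higher, with adjusted p = 0.111, 0.464 and 0.111 with an estimated correlation. The count of 105 moved to between 27 (without the CB males of 32C) and 139 (without the CB males of 64C) with a group left out, and another split of the same 8 groups gave 185.

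From 32C to 64C, 3 genes rose and 17 fell (edgeR, 4 groups each). Gata4, a transcription factor of the primitive endoderm, rose from 3.98 ± 2.91 to 71.8 ± 52.1 CPM (SD, n = 4; log2 change 4.26, SE 0.893). Pth1r, the receptor of parathyroid hormone, rose from 0.062 ± 0.0607 to 43.6 ± 44.4 CPM (9.44, SE 1.84) and Numb, a cell-fate regulator, by 5.31 (SE 1.09). Nlrp14, an oocyte gene, fell by 5.49 (SE 1.09), Tnfsf13b, a cytokine gene, by 6.32 (SE 0.763), Zscan5b by 5.90 (SE 0.903), and Slc27a5, Clmp, Jazf1, Prr23a1, Fbxw15 and Tex15 to at most 2 counts. Primitive endoderm (camera adjusted p = 0.000469; 7 rose and 1 fell of 20), FGF and ERK feedback (0.0093; 3 rose of 16), ribosomal protein (0.0093; 0 of 20) and trophectoderm genes (0.0499; 2 rose of 19) were higher and oocyte genes lower (0.0142; 4 fell and 1 rose of 20), counted as adjusted over the list alone. The oocyte genes had a mean log2 change of -0.725 and a median of 0.253, so the typical member did not fall. With an estimated correlation they had adjusted p = 0.54, 0.54, 0.722, 0.722 and 0.654. The count of 20 moved to between 4 (without the BC females or CB males of 64C) and 55 (without the BC males of 64C) with a group left out, and another split of the same 8 groups gave 19. In each of the 6 steps, the lists not named did not pass with camera. With fry, maternally expressed imprinted genes were lower from the oocyte to 2C (adjusted p = 0.00595) and p53 and stress genes lower from 2C to 4C (adjusted p = 0.014).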

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

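The explanation of carry-over below was tested after the values were seen. The limit for a distant cell came from simulated normal values, of which about 1 set in 20 would exceed it. Skewed measures such as Xist CPM need not keep that rate. In 5 of 53 combinations of group and measure, 1 cell lay beyond that limit from the other cells of its group. They are cell 80 of the 32C CB wild-type males (paternal X share 0.0117, next 0.0024), cell 64 of the 64C BC wild-type females (paternal autosomal share 0.4958, next 0.509), cell 51 of the 64C CB wild-type females (Xist 533 CPM, next 74.9), cell 9 of the 8C CB females labelled mutant (Xist 80.6 CPM, next 21.2) and cell 14 of the 8C BC wild-type males (depth 5.32M, next 9.82M).

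Cells 7 and 9 of the 8C females labelled mutant hold Xist reads that their label excludes. The paternal share of Rlim argues against wild-type cells under a mutant label but does not rule them out. It was 0.529 and 0.542 in the 2 cells, against 0 to 0.311 in 4 wild-type CB cells of 8C. The 5 other mutant cells had 0.321 to 0.590. The test rests on a single gene, the 2 ranges nearly meet, and the Xist reads of both cells were mostly paternal. A small carry-over from wild-type cells could not be decided by the limit of 10% set for the test. Their Xist levels were 3.74% and 14.2% of the highest wild-type cell of 8C (566 CPM), on either side of it. That cell is of BC, where the paternal Xist (share 0.9955 in BC females of 8C) is Cast and would count as maternal in CB cells. The mostly paternal Xist reads of cells 7 and 9 thus argue against BC cells as the source. The 4 wild-type CB cells of 8C had 4.50 to 80.1 CPM. Against these, cell 9 stands at the level of the highest and cell 7 (21.2 CPM) within the range, which argues against a small carry-over from them. Carry-over from CB cells of other stages was not tested.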

How the results depend on the processing

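The split test of the X shares per gene was chosen after its result was seen, and the other splits before. No paired analysis was possible because the labels do not say what the number in a title marks, and each group was summed to 1 sample, which leaves no number to pair by. The pairs used in the tests are stages, crosses or sexes. The paternal X share of wild-type females kept its fall with stage (r from -0.915 to -0.726 with a stage left out), females labelled mutant stayed above wild type (0.122 to 0.218 with a stage left out), and X dosage in those females stayed above 0 (0.336 to 0.426). What depth and the number of cells per group (1 to 25) limit was not tested.

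DESeq2 called more genes: 202 for mutant females, 309 for mutant males, 247 for the interaction, 74 for females against males, 786 for the crosses, and 3041, 1317, 1198, 810 and 525 from 2C to 4C through 32C to 64C. With each cell weighing the same, the counts were 4 for mutant males, 8 for females against males, 0 for the crosses, 6728 from the oocyte to 2C, and 3581, 388, 316, 324 and 114 for the later steps. Females against males gave 3 from 8C to 64C alone. From 8C to 16C, RLE factors gave 203. With sex and cross as covariates, 4C to 8C gave 185 and 8C to 16C gave 62. Without the 2-cell female of disputed cross, 32C to 64C gave 13. X dosage of females against males was 0.144 with the authors' normalized signal. Of 208 list tests, 47 passed with camera and 4 with an estimated correlation, and 21 of 189 passed with fry, which gave no value for mutant males. Of 6661 values of 253 named genes, 5831 kept their call, 807 lost it, 23 gained it and 0 reversed. The cause was not tested.

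With a stage or group left out, the counts ranged from 0 to 1 for mutant females (1 without 8C), 1 to 6 for females against males (3 without 2C, 2 without 4C, 1 without 8C, 16C or 32C), and 2 to 6 for the crosses (6 without 64C). X dosage of females against males ranged from 0.0838 to 0.128. From the oocyte to 2C the range was 2491 (without Cast oocytes) to 4613, with 2879 without B6 oocytes. From 2C to 4C it was 849 (without 4C BC females) to 1987, with 1020 without 4C CB females and 940 without 4C BC males. From 4C to 8C it was 0 (without 4C BC males) to 179 (without 16C CB males), with 1 and 15 without 4C BC or CB females, 159 and 150 without B6 or Cast oocytes, and 127 without 8C CB males. From 8C to 16C it was 6 (without 16C BC or CB females) to 402 (without 8C BC males), with 17 without 8C CB males, 247 without 8C BC females, 31 without 16C BC or CB males, 216 and 205 without B6 or Cast oocytes, 65 without 2C BC females, 83, 82 and 86 without 4C BC females, CB females or BC males, and 84 without 32C CB females. From 16C to 32C it was 27 (without 32C CB males) to 139, with 36 and 51 without 16C BC or CB males, and 39 and 31 without 32C BC or CB females. From 32C to 64C it was 4 (without 64C BC females or CB males) to 55 (without 64C BC males), with 13 without 2C BC females or 32C BC females, 12 without 2C CB males, 8 without 4C BC females, 9 and 31 without 16C BC or CB males, and 5 without 32C BC males. Leaving out a stage gave no value for the interaction, as no residual degrees of freedom remain.

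Other splits of the same groups were used to gauge what chance gives, though each also moves real differences into the spread. Females against males gave 5 genes against at most 0 in 50 splits and the crosses 3 against at most 0 in 50, each with 1 split as large, the real one. Xist, Eif2s3y and Ddx3y among the 5 follow the sex of a cell, so their loss in other splits was fixed in advance. From 2C to 4C 1602 stood against 424, from 4C to 8C 81 against 5, and from 32C to 64C 20 against 19, each reached by 1 of 35 splits. From 8C to 16C 135 stood against 148 and from 16C to 32C 105 against 185, each reached by 2 of 35 splits, so chance is not excluded there. Nor is it excluded from 32C to 64C, where the real count of 20 barely exceeded the 19 of another split. For mutant females the splits decide nothing, since the real count was 0 and 8 of 8 splits reach it. For the share per gene there were too few splits to tell: 1 of 8 reached 13 genes, against at most 0 in the others.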

Other observations

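The tests of the number of X chromosomes and of shared reads for the Fthl17 genes, and of the Cast allele for Xist, were chosen after the result was seen. Fthl17 genes, ferritin-like genes on the X, had 229 and 789 CPM summed over the family in BC and CB females at 2C, 72.1 and 156 at 8C and 6.56 and 38.98 at 64C. Wild-type males had 0 and 53.6 at 2C, 0.0850 and 3.93 at 8C and 36.8 and 0.457 at 64C. Females labelled mutant had 129 CPM at 8C, 157 at 16C, 178 at 32C and 112 at 64C.

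Higher Fthl17 expression in females was weighed against 3 explanations. A 2-fold dose from 2 equally active X chromosomes was ruled out for the 5 clustered genes. Their median log2 change was 5.897 (5.64 to 6.06, SE 0.965 to 1.099). Unequal use of the 2 X chromosomes is not covered by that test. For Fthl17a the direction itself is not settled. Its fitted log2 change was 2.434 (SE 1.961), higher in females in 5 of 11 pairs. Its pooled level was lower in wild-type females (0.617 CPM) than in wild-type males (3.13 CPM). Reads shared between copies were ruled out as well: counts summed over the family differed by a median log2 ratio of 4.78, higher in females in 10 of 11 pairs, the exception being 64C BC (-2.32). Expression from the paternal X could not be decided by the limit set, 0.85 for the median paternal share, which was 0.639 over 2 genes. That median mixes Fthl17f of the cluster with Fthl17a, which lies elsewhere on the X and had 0.337 over 3 groups. Fthl17f, the only clustered gene with a share, lay above the limit, with 0.942 over 12 groups and 0.998 in females labelled mutant. The other clustered genes had no share, so the cluster as a whole stays open.

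Xist at 64C was lower in CB than in BC wild-type females. BC had 6.94 times the level of CB in the summed counts. The CB sum rests largely on cell 51 (533 CPM, next 74.9), and the medians over cells were 803 CPM in BC and 44.3 CPM in CB. A loss of Cast reads was ruled out, since it would lower BC more: the Cast allele gave 0.988 to 0.999 of the Xist reads in 6 BC cells and at most 0.0896 in the 4 CB cells with a share. A lower depth of the CB cells was ruled out as well, with a median depth of 104.9% of that of BC. The ratio of BC to CB was 1.82 at 4C, 5.29 at 8C, 0.717 at 16C and 2.095 at 32C, and strain or embryo were not separable here.

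A hypothesis on distance was stated before its test: genes near Xist are lower first. Across 103 X-linked genes, Spearman's rho between distance from Xist and paternal share in wild-type females was 0.131 at 8C (permutation p = 0.179), 0.419 at 16C (permutation p = 0.0001, the smallest that 10000 resamples can give; adjusted p = 0.0004), 0.55 at 32C (adjusted p = 0.0004) and 0.201 at 64C (adjusted p = 0.082). In females labelled mutant it was 0.0187, 0.0553, 0.251 (adjusted p = 0.0312) and -0.039. The 8 relations form a single family, p-values are two-sided, and genes are not independent replicates. At 16C the median share was 0.240 in the 16 genes within 20 Mb and 0.376 in the 87 beyond, and at 32C 0.194 and 0.372. The prediction held at 16C. The source of the relation in females labelled mutant at 32C was not tested.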
